A study of Ovis aries with 2 samples.

How the data were processed

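Messenger RNA of rumen papillae was sequenced in 2 libraries of sheep (Ovis aries), titled A and B. Papillae are the finger-like projections of the rumen wall, lined by a stratified squamous epithelium through which the products of microbial fermentation are absorbed. Per the series' design text, papillae were sampled through an endoscope passed by mouth in 4 Coopworth ewes after a fast of 4 or 24 hours, whereas per the labels' protocols the papillae were recovered at slaughter and frozen; the sources used here do not say which account applies to which library. Per the labels' protocols, total RNA was extracted from about 10 mg of tissue, libraries were made with a stranded poly(A) kit (TruSeq Stranded mRNA), and the pool of both was sequenced on an Illumina MiSeq with a Nano kit as 150 bp paired reads, a format of low output.

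The deposited values are whole-number counts per gene, not normalized, with 1 file per library. Trim Galore 0.3.7, STAR (version not given in the sources used here) and HTSeq 0.6.1p1 are named by the submitters' processing notes. The genome build, the annotation release and the strand setting of the counter are not given in the sources used here. Each file lists 25197 Ensembl sheep gene identifiers, followed by the counter's own summary rows. These summary rows were left out of all library sizes and tests. Of all counts in a file, summary rows included (148700 in library A and 154032 in library B), those in no feature made up 29.6% in A and 30.3% in B, and ambiguous ones 0.487% and 0.440%. The summary rows for unaligned, non-uniquely aligned and low-quality reads stood at 0 in both files, so the mapping rate cannot be read from them, and genes with near-identical copies may have lost reads before counting.

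The files do not pair the identifiers with gene names, and 0 of the 25197 identifiers were found in the gene table used here, whose 35057 entries carry no Ensembl identifiers. Gene names, coordinates, gene lengths and GC content were therefore not used. For this reason 23 gene lists fixed before the data were examined (epithelial layers, junctions, transport, ketogenesis, cholesterol synthesis, fasting response, stress, immune, stromal, muscle and blood markers and others) could not be scored, and the planned rule for named genes, which required a gene symbol, named none. In its place at most 4 identifiers are printed, chosen after their values were seen: the 2 genes with the smallest p on the side of each library.

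Both libraries carry the same tissue label and were treated as 1 group. The labels give neither fasting time nor animal for either library, so no fasting comparison was made, and no mean with a standard deviation is given. Whether the libraries came from separate animals, biopsies or preparations is not stated, and p-values here measure only the difference between these libraries against counting error.

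Total counts over genes were 103999 in A and 106750 in B. CPM values, counts scaled to a library total of 1e6, were computed on these totals, with exact Poisson 95% intervals, and shares of counts with exact Clopper-Pearson intervals. A gene at 0 counts may have had up to 3 counts' worth of expression, 28.8 CPM in A and 28.1 CPM in B. Intervals and limits cover counting error only, since the reads carried no molecular identifiers.

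Differences between the libraries were tested gene by gene with an exact two-sided binomial test of the raw counts given the gene's total, with effective library sizes from trimmed mean of M values (TMM, edgeR 4.0.16) and Benjamini-Hochberg adjustment over the 3076 genes with a total of at least 10 counts, at a threshold of 0.05. The quasi-likelihood test of edgeR has no residual degrees of freedom for 1 library against 1. Log2 ratios used a prior of 0.5 counts per library. Agreement was measured as Pearson's r and Spearman's rho across genes of log2(CPM + 1), for genes with a mean of at least 10 counts. Homogeneity was measured by a chi-square test of the gene counts of both libraries, divided by its degrees of freedom, and by the common dispersion of edgeR with both libraries as 1 group, printed as a coefficient of variation. At their main settings, the agreement, the chi-square and the gene test were set beside 100 random splits. In these, every gene's pooled count was divided between the libraries by chance alone. The dispersion was set beside 100 simulated pairs of libraries, drawn from the pooled gene shares with counting error alone.

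The gene test was tested on simulated data with the real gene means and 200 changed genes in each of 20 draws over 3076 genes. A changed gene was raised in A and lowered in B, or the reverse, by the square root of its fold. Its simulated total therefore exceeded its real total, by more at larger folds, while the count classes below use the real total. Of genes with a total of 100 counts or more it recovered 87.5% of 2-fold and 100% of 4-fold changes, of genes with 20 to 99 counts 12.7% and 76.4%, and of genes with 10 to 19 counts 1.41% and 22.0%. Of all its calls, 3.12% were false. The simulated libraries varied by counting error alone, so these rates do not cover variation between libraries beyond it. The 20 draws together gave 2567 calls, where the real comparison gave 2. An adjustment over many changed genes is easier to pass. For this reason, and because of the raised totals, the rates are too high for the real comparison. The dispersion estimate returned a median of 4.90% where 5% had been simulated and 9.77% where 10% had.

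Alternatives covered the scaling, the count minimum, the pseudocount, thinning of library B to the total of A, the most abundant genes, assumed variation between libraries, and each library alone. Computation used R 4.3.3, DESeq2 1.42.0 (size factors only), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.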

Results

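Poly(A) RNA from rumen papillae of sheep was counted per gene in 2 libraries, A and B, with 103999 and 106750 counts over genes. The series title presents sampling of papillae through the mouth as a repeatable method. The values below therefore describe which part of the transcriptome each library covered and how closely the libraries agreed. Fasting time and animal are not given for either library, so no fasting effect was tested. Genes appear by Ensembl identifier, because neither the files nor the gene table used here pair the identifiers with names.

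At least 1 count was found for 8368 genes in library A and 8444 genes in library B, of 25197 listed. Of these, 7006 genes were detected in both libraries and 9806 in at least 1 of them. Most detected genes had few counts. The median count of a detected gene was 3 in each library, and 26.8% of the detected genes in A and 26.4% in B had exactly 1 count. Genes with 10 counts or more numbered 1596 in A and 1639 in B, and genes with 100 counts or more 134 and 140. When the counts of library A were thinned at random to 50%, 6736 genes remained, and 6824 remained in library B. The remaining 15391 genes had no count in either library, which at the pooled depth allows a level of up to 14.2 CPM for each.

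**Figure D1:**
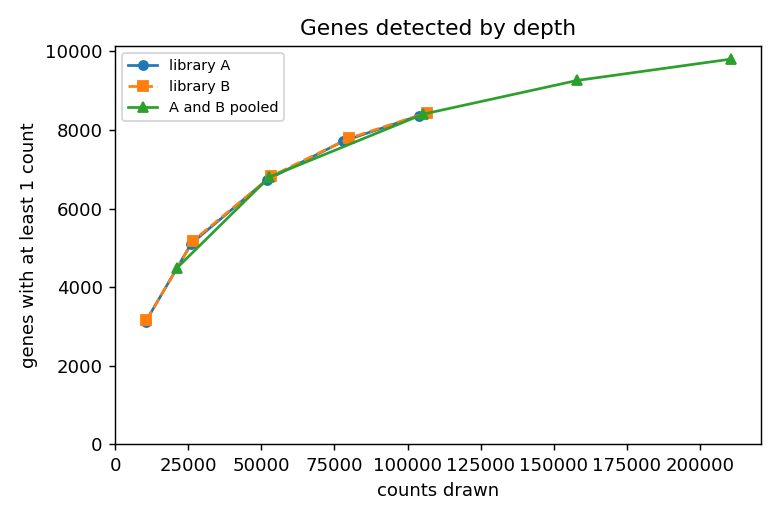
Genes with at least 1 count (vertical axis) against the number of counts drawn at random (horizontal axis), for library A, library B and both pooled. The curves of A and B lie close together, and detection still rose between 75% and 100% of the counts, from 7715 to 8368 genes in A and from 9262 to 9806 genes in the pooled counts.

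A small set of abundant genes supplied much of each library. The 10 most abundant genes took 18.5% of the counts in A (95% exact interval 18.3 to 18.7) and 18.7% in B (18.4 to 18.9). The 100 most abundant genes took 42.9% and 43.3%, and 50% of the counts came from 172 genes in A and 164 in B. A level of at least 1000 CPM was reached by 132 genes in A and 134 in B. The 10 most abundant genes of A were also the 10 most abundant of B, and 95 of the 100 most abundant were shared. The most abundant gene in both was ENSOARG00000000016, at 35193 CPM in A (95% Poisson interval 34062 to 36352) and 38454 CPM in B (37287 to 39649).

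The libraries were next compared gene by gene. The labels do not say whether they are separate samplings, so their agreement does not measure how repeatable sampling through the mouth is. Across the 1554 genes with a mean of at least 10 counts, Pearson's r of log2(CPM + 1) was 0.932 and Spearman's rho was 0.797. These are correlations across genes, which are not independent replicates. Random splits of the pooled counts, in which the libraries differ by counting error alone, gave a median r of 0.936 with a 95% range of 0.930 to 0.941, and a median rho of 0.806 with a range of 0.794 to 0.818. The observed values lay inside both ranges, toward their lower ends. Of the 100 splits, 88 gave an r as high and 94 a rho as high. The chi-square over the same genes, given below, did exceed the splits. Over all 9806 detected genes r was 0.576, against a median of 0.576 in the splits, and in the 271 genes with a mean of at least 50 counts it was 0.983.

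Of 3076 genes tested, 2 differed between the libraries past an adjusted p of 0.05 (exact binomial test, Benjamini-Hochberg), and both were higher in library B. They were the most abundant genes of the data set. ENSOARG00000000016, with 3660 counts in A and 4105 in B, was 1.11-fold higher in B (95% exact interval 1.06 to 1.16, adjusted p = 0.00753). ENSOARG00000000035, with 3098 and 3498 counts, was 1.12-fold higher in B (1.07 to 1.18, adjusted p = 0.00753). No gene was called higher in A at this count minimum of 10. The smallest p-values on that side belonged to ENSOARG00000010388, with 21 counts in A and 3 in B (ratio of A to B 7.06, exact interval 2.11 to 37.0, adjusted p = 0.0908), and to ENSOARG00000021080, with 381 and 290 counts (ratio 1.33, exact interval 1.13 to 1.55, adjusted p = 0.142). The first passed with a minimum of 20 counts (exact test, adjusted p = 0.0459) and the second with a minimum of 50 (exact test, adjusted p = 0.0284). An unadjusted exact p under 0.05 was reached by 129 genes, where splits by counting error alone gave a median of 113 and a 95% range of 97 to 136. The splits called at most 1 gene. There is no replicate check on these calls. The coefficient of 5.89% used below was estimated from the difference between these same libraries. It absorbs that difference and gives no independent check. Scaling to total counts ended both of them, at an adjusted exact binomial p of 0.0814, with ratios of 1.09 and 1.10 in place of 1.11 and 1.12. Allowing for variation between libraries also ended them: edgeR's exact test called 0 genes with a coefficient of variation of 5.89%, estimated without the 10 most abundant genes (smallest adjusted p = 0.528, 82 genes at an unadjusted exact p under 0.05), and 0 with an assumed 10% (smallest adjusted p = 0.856, 61 genes unadjusted).

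**Figure D2:**
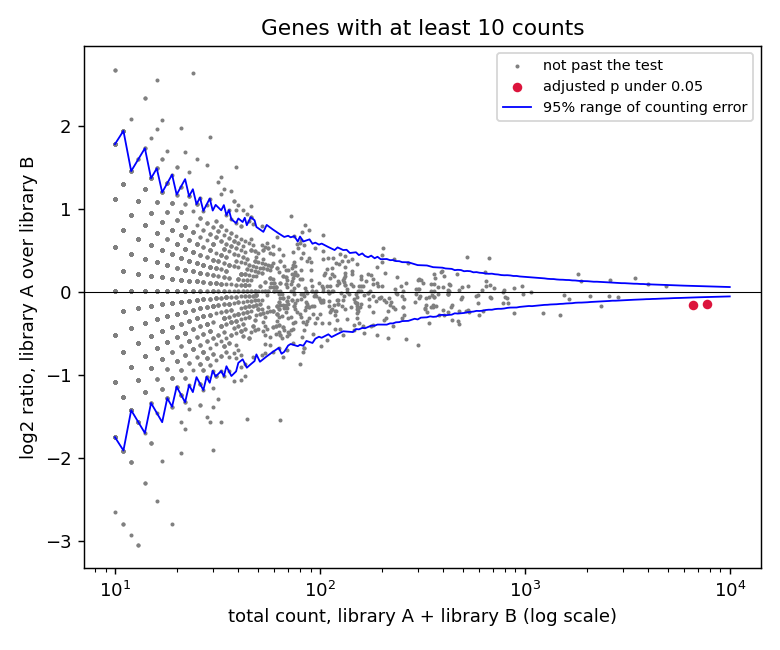
Log2 ratio of library A over library B (vertical axis) against the total count of the gene in both libraries on a log scale (horizontal axis), 1 point for each of the 3076 genes tested. Blue lines bound the 95% range that counting error alone gives, and the 2 red points are the genes past the adjusted p of 0.05, both below 0, that is, higher in B.

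Folds between the libraries, which include counting error, were larger at lower counts. Counting error alone widens folds as counts fall, so this does not show that rarer genes differed more beyond it. Genes with a total of 200 counts or more, 139 in number, differed by a median of 1.09-fold in either direction, and the largest difference among them was 1.57-fold. In the 132 genes with 100 to under 200 counts the median was 1.12-fold and the largest 1.61-fold. None of these 271 genes differed by 2-fold or more. In the 1283 genes with 20 to 99 counts the median was 1.25-fold, and 75 of them differed by at least 2-fold. In the 1522 genes with 10 to 19 counts the median was 1.41-fold, and 303 of them differed by at least 2-fold, none past the test. At that depth a 2-fold difference was rarely detectable, as 1.41% of simulated ones were recovered. Of simulated 4-fold and 8-fold differences, 22.0% and 72.1% were recovered. These rates are too high for the real comparison, since 200 genes were changed in each draw, which made the adjustment easier to pass. The largest real difference in this class, 8.26-fold, was not past the test.

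Over the 1554 genes with a mean of at least 10 counts, the libraries differed by more than sampling noise, so gene levels are given for each library. The chi-square per degree of freedom was 1.16 (chi-square p = 9.73e-06), above the highest of 100 splits by counting error alone (1.11). The classes by abundance that follow were not part of the planned test. By abundance, the ratio was 3.11 in the 68 genes with a mean of 200 counts or more and 1.61 in the 71 genes with a mean of 100 to 200, both above the 95% ranges of the splits, which ended at 1.27 and 1.23. In the 1415 genes with a mean of 10 to 100 counts it was 1.04 (chi-square p = 0.119), inside the 95% range of the splits (0.922 to 1.07) and also inside the range of 1.02 to 1.17 simulated with the 6.38% coefficient of variation of the genes with a mean of 100 counts or more. Expressed as a common coefficient of variation over all 1554 genes, the spread beyond counting error was 5.83% (95% interval over resampled genes 4.52 to 6.74). Simulated libraries without such spread gave at most 2.37%. Since the 1415 genes with a mean of 10 to 100 counts did not exceed counting error, this value need not hold for a typical gene.

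**Figure D3:**
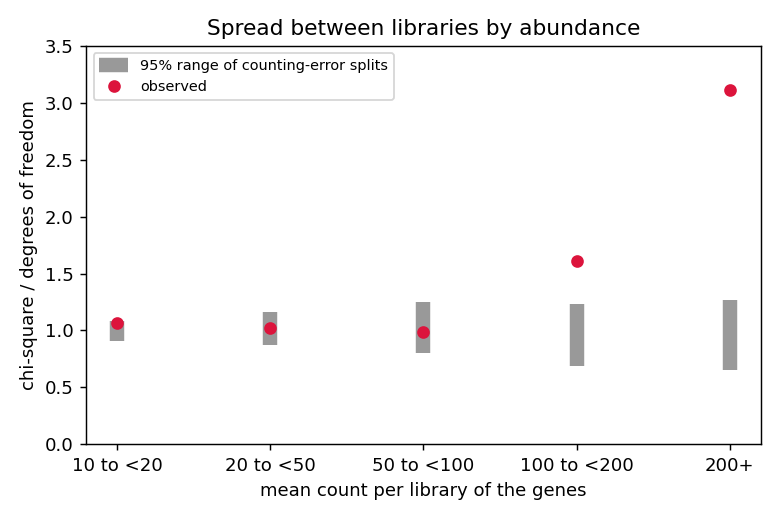
Chi-square per degree of freedom between libraries A and B (vertical axis) for genes grouped by mean count per library (horizontal axis), in classes that were not planned. Red points are the observed values and grey bars the 95% range of 100 splits by counting error alone, and the points rise above the bars in the 71 and 68 genes of the highest classes, at 1.61 and 3.11.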

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

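The tests in this part were all chosen after the values were seen. Counts that fell in no annotated feature, which no comparison above uses, made up 29.6% of all counts in library A, summary rows included, and 30.3% in library B. Ambiguous counts made up 0.487% in A and 0.440% in B, and the interval of their difference includes 0 (chi-square p = 0.0584). The share in no feature was 0.682 percentage points higher in B (95% interval 0.355 to 1.01), so counting error alone does not account for the difference, although with 1 library on each side it has no replicate check. A count on the wrong strand of this stranded kit would leave mostly antisense reads in genes, and at least 69.3% of counts were assigned to genes in each library, which argues against it as the main source of the counts in no feature. Transcribed regions absent from the annotation, introns and genomic DNA stay open and were not tested, since no annotation of these identifiers was used; no biological explanation was tested, because the labels give both libraries the same group.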

How the results depend on the processing

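Alternatives were fixed before the data were examined, except 4 chosen after seeing them: genes with a mean of 10 to 100 counts, and edgeR's exact test with no variation beyond counting or with either estimated coefficient. Both estimated coefficients came from the difference between these libraries, so tests that use them are not an independent check. The number of genes differing between libraries was 2 and became 0 with total counts, without the 10 most abundant genes (which removes both called genes), and in edgeR's exact test with the estimated coefficient (5.83%, or 5.89% without the 10 most abundant genes) or an assumed coefficient of 0.1, 0.2 or 0.4. It rose to 5 with at least 20 counts and 6 with at least 50 counts, where fewer genes were tested (1554 and 527), and both original genes stayed among them; at 20 counts ENSOARG00000010388 passed as higher in A (exact test, adjusted p = 0.0459), and at 50 counts ENSOARG00000021080 did (exact test, adjusted p = 0.0284). DESeq2 size factors, upper quartile, no filter, library B thinned to the total of A, and edgeR's exact test with no variation beyond counting gave 2 or 3. DESeq2 size factors and upper quartile both set A and B to equal size, so they are the same scaling and not separate checks. The size of A over B was 0.991 with TMM and 0.974 with total counts, so the calls depend on the scaling. Each of the 4 printed genes kept its direction in the settings of the binomial test that included it (7 alternatives, or 8 for ENSOARG00000021080). Genes detected in both libraries fell from 7006 to 2620 at 5 counts and 1315 at 10 counts, by construction. The number of genes that make up 50% of the counts, taken on the mean share over both libraries, rose from 168 to 339 once the 10 most abundant were left out. Pearson's r went from 0.932 to 0.945 with a pseudocount of 25 CPM, 0.983 at a mean of 50 counts or more and 0.576 over all detected genes. The chi-square per degree of freedom stayed past the threshold at a mean of 50 counts or more and without the 10 most abundant genes, but not at a mean of 10 to 100 counts (1.04). Depth limits all results for genes under about 100 counts. Corrections for gene length and GC content, and all shifts of gene lists, were not run, because the identifiers were matched to no gene table.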

Other observations

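The tests in this part were chosen after the values were seen, except the chi-square test over genes with a mean of at least 10 counts, which was planned. Many genes were detected in 1 library alone, 1362 in A and 1438 in B, and a reader could take them for genes expressed in only some papillae. None of them had more than 8 counts, 67.5% of those of A and 65.3% of those of B had exactly 1, and together they held 2.04% and 2.14% of the counts. Counting error at this depth was tested as the explanation: 1858 of these genes had a pooled count of 1 and would fall in 1 library alone under any split, so they carry no information. The other 942, with a pooled count of 2 or more, lay within the range of 900.5 to 1017 that 95% of the random splits gave. Their number is therefore consistent with chance, which says nothing about any gene among them.

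The libraries differed beyond counting error by a small amount, and the tables bear on where that comes from. That the files hold the same library deposited again is argued against by the chi-square per degree of freedom of 1.16, which no random split reached. The 10 most abundant genes alone are not the whole source, since the 129 genes with a mean of 100 counts or more that remained without them still gave 1.96 (chi-square p = 5.36e-10). Those 10 were picked by level and not by difference. Whether a few of the 129 carry most of the remaining spread was not tested. Whether the less abundant genes share the same spread cannot be told apart from no spread at all: at a mean of 10 to 100 counts the ratio was 1.04, inside both the range of 0.922 to 1.07 from counting error alone and the range of 1.02 to 1.17 simulated with the 6.38% coefficient of the abundant genes. Separate preparations of the same RNA, neighbouring papillae, separate animals and different fasting times all stay open as sources, as the labels assign none of them to either library.

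Pooling the libraries left 1858 genes with exactly 1 count among 9806 detected. From the genes seen with 1 and 2 counts, the Chao estimator gave a lower bound of 10304 genes that receive reads from A alone and 10298 from B alone, and 11288 from the pooled counts. When the pool was thinned to the 103999 counts of A, the bound had a median of 10196 over 20 draws (10009 to 10375), a range that holds the bounds of both libraries. The bound thus moved with depth, and reads of genomic DNA, left untested, would enter it too, so it does not count the genes expressed in papillae.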
